A study of Gluconobacter oxydans with 2 samples.

How the data were processed

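RNA sequencing libraries were available from 2 strains of Gluconobacter oxydans WSH003, an acetic acid bacterium that oxidises sugars and sugar alcohols incompletely in the periplasm. One library came from the wild type (WT) and 1 from a strain that overexpresses pqqB (TB). Both cultures were sampled in exponential growth, and total RNA was taken after lysozyme treatment, per the labels' protocols. The series' design text names the Illumina MiSeq as the sequencer. The submitters' processing notes name FastQC 0.11.3, cutadapt, Bowtie2 and Cufflinks without their roles, order or settings. The genome build and the annotation are not given in the sources used here.

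The deposited table holds 1 FPKM value (fragments normalised to gene length and library total) per gene and library for 3543 genes, per the file headers. It lists a gene identifier and a locus on a sequence named 1, whose last position is 3602407. Locus starts were counted from 0 in the file, since the difference of end and start was a multiple of 3 for 2166 of the 2212 genes with a locus of their own. Positions are given here counted from 1. Own-locus lengths are therefore mostly lengths without untranslated regions, although a multiple of 3 does not by itself make a gene coding. The other 1331 genes share 552 merged loci of up to 6 genes, and their own ends are not given. How fragments were divided among the genes of a merged locus, and whether strand was used, is not given in the sources used here. The identifiers are not paired with gene names or products in the files used here, and no annotation was used. The 28 lists of functional classes fixed before the data were examined were therefore not applied. Which identifier is pqqB was not determined.

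Fragment counts were recovered from the deposited FPKM values. Genes of equal length differed by whole multiples of the FPKM of 1 fragment. From 540 bp upwards, fragments per FPKM rose linearly with length. The slope gave a normalising total of 1490600 fragments for TB and 4479600 for WT, and the intercept gave estimated mean fragment lengths of 225 bp for TB and 219 bp for WT. Shorter lengths were followed downwards to 174 bp. Within a tolerance of 0.05 fragments, 99.9% of the 1945 TB values above 0 and 99.8% of the 1958 WT values above 0 were whole. The fit sought whole numbers in these same values, so this share is not an independent check. That holds above all below 540 bp, where the step was chosen length by length. The recovery covers 1993 genes with a locus of their own, holding 1010875 TB and 3055841 WT fragments. The 219 shorter genes with a locus of their own have no recovered count. On data simulated for the own-locus genes, all fragment numbers came back within 1% or 1 fragment (100% of 1943 TB and 1953 WT values). The intervals held the true fold for 96.1% of 1754 genes simulated without a change, and for 94% to 96% of 50 genes at each of 4 other fold sizes. The simulation drew whole fragments with counting error alone, using the totals and mean fragment lengths inferred above. It therefore checks the procedure, not whether the real counts carry only counting error.

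Values were compared as log2((TB FPKM + 1)/(WT FPKM + 1)), with a pseudocount of 1 FPKM. This scale understates the change of low genes above 0. For a gene listed at 0 in 1 library the ratio depends on the pseudocount and can be large. At 180 bp, 1 TB fragment was worth 180.3 FPKM. Genes entered the comparison when their mean over both libraries reached 128.3 FPKM, the 25th percentile of genes with a mean above 0. There is 1 library per strain, so no difference has a replicate check and no p-value was computed. The design assumed no particular unit, and differences are described by size, with 2-fold as the threshold. For own-locus genes, an exact 95% interval of the fold (Clopper-Pearson, on the TB share of both libraries' fragments) is given. These intervals cover counting error only, not variation between cultures or libraries, and PCR copies are not independent molecules. A count of 0 allows up to 3 fragments. For genes in merged loci, the shortest length from 174 bp upwards, in steps of 3 bp, at which both values were whole within 0.03 fragments (plus the rounding of the file) gave the fewest fragments behind the value. This floor assumes a gene of at least 174 bp and whole fragments, which could not be checked in merged loci.

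Before the data were examined, the rule for named genes was fixed. It takes every pqq gene, members of the functional lists, and the 12 genes with the largest and the 12 with the smallest log2 ratio among those passing the low-value minimum and above 0 in both libraries, with at most 2 identifiers named per direction where no product name is known. It also takes the 10 genes with the highest mean and genes listed at 0 in 1 library and above the 75th percentile of the other, which are given here as counts and ranges. Other genes are described by position, and these, the loci of equal length included, were chosen after their values were seen. Recovery of fragments and runs of neighbouring genes were also added after the values were seen. A run is at least 3 consecutive passing genes with a log2 ratio of at least 0.5 in 1 direction. They were compared with 1000 shuffles of the gene order. Alternatives covered the pseudocount, the low-value filter, 4 scalings and the fold threshold. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.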

Results

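The transcriptomes of 2 strains of Gluconobacter oxydans WSH003 were compared, the wild type (WT) and a strain overexpressing pqqB (TB). The pqq genes make pyrroloquinoline quinone (PQQ), the redox cofactor of membrane-bound dehydrogenases with which this bacterium oxidises glucose, sorbitol and ethanol in the periplasm. The series concerns strains that differ in PQQ production, and the comparison asks which transcripts differ when pqqB is overexpressed in exponential growth. Each strain was represented by 1 RNA sequencing library, so the differences below are between 2 libraries and have no replicate error. FPKM values were given for 3543 genes, with a median of 197.3 in TB and 197.7 in WT. The WT library was 3.01 times deeper, with a normalising total of 4479600 fragments against 1490600 in TB. The median own-locus gene above 0 was covered by 725.5 fragments in WT and 247 in TB.

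Expression was closely alike in both libraries for most genes. Of the 2430 genes that reached the low-value minimum, 2246 (92.4%) differed by less than 1.5-fold. The median log2 ratio of TB to WT was 0.02. Across the 2415 of these genes above 0 in both libraries, Pearson's r of log2(FPKM + 1) was 0.973 and Spearman's rho 0.952, across genes, which are not independent replicates. The 10 own-locus genes with the most fragments held 12.9% of the own-locus fragments in TB and 12.3% in WT, and their log2 ratios lay between -0.40 and 0.36. The spread between the libraries was larger than counting error in well-covered genes. Among the 379 own-locus genes with 400 to 800 TB fragments, the robust SD of the log2 ratio was 0.20, while counting alone gives 0.07. Among the 60 genes with 1 to 10 TB fragments these values were 0.82 and 0.73. Along the sequence, over 18 windows of 200 kb with at least 20 genes, the median log2 ratio ranged from -0.09 to 0.11. Medians were positive in every window that starts at 0 to 800 kb and of mixed sign beyond. A regional trend was not tested.

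**Figure D1:**
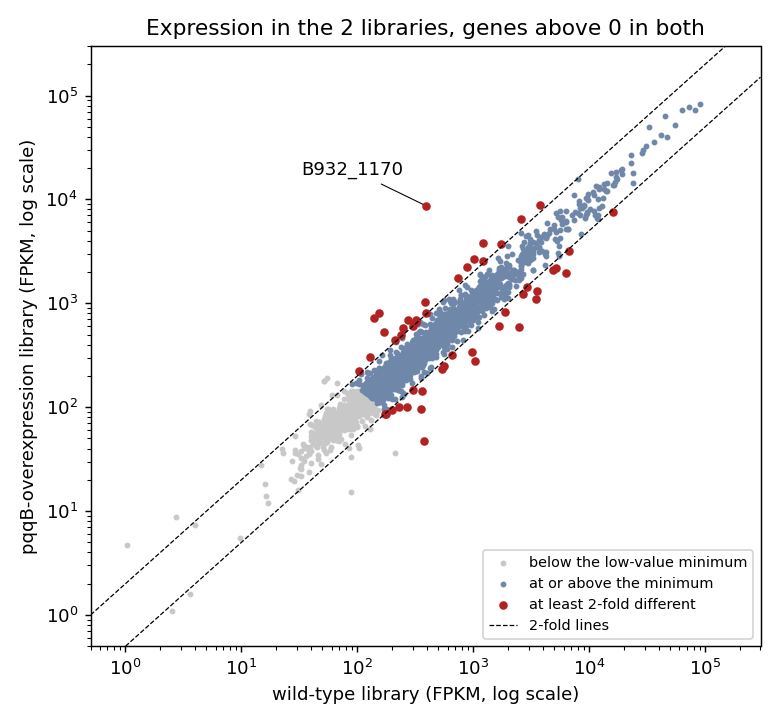
FPKM of each gene above 0 in both libraries, wild type on the x axis and overexpression strain on the y axis, both on log scales; grey points lie below the low-value minimum, blue points at or above it, and red points differ at least 2-fold (dashed lines). Most genes lie between the 2-fold lines, and B932_1170 stands apart at 8665 FPKM in TB against 392.2 in WT.

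B932_1170, in a merged locus of 4 genes at positions 1182610 to 1185576, stood at 8665 FPKM in TB and 392.2 FPKM in WT, a 22.1-fold difference (log2 ratio 4.46). The next-largest log2 ratio among passing genes above 0 in both libraries was 2.40. Of lengths from 174 bp upwards, both values of B932_1170 were whole fragments at 37, the shortest of 594 bp. If the gene is at least 174 bp long and holds whole fragments, at least 4780 TB and 660 WT fragments lie behind the ratio. At that length the 95% counting interval of its log2 fold was 4.35 to 4.59. The other 3 genes of the same locus had log2 ratios of 0.04 to 0.13. The 5 genes before the locus and the 1 after it, together 6 genes, ranged from -0.44 to 0.21. The next gene after those was listed at 0 in TB and had 2 WT fragments. How fragments were divided among the genes of this locus is not given in the sources used here. The overexpressed gene itself is the natural check of the strain labels, but the identifiers carry no gene names in the files used here, so the value of pqqB is not stated.

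**Figure D2:**
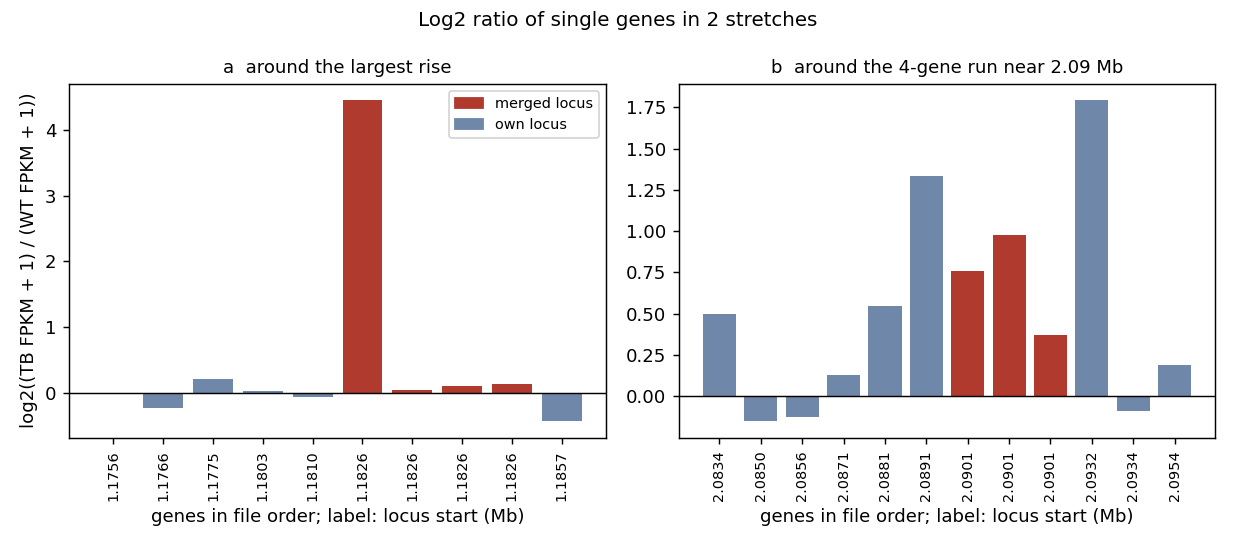
Log2 ratio of TB to WT FPKM (pseudocount 1) of consecutive genes in file order, labelled with the start of their locus in Mb; red bars are genes in merged loci and blue bars genes with a locus of their own. In panel a, B932_1170 reaches 4.46 while the other 3 genes of its locus lie at 0.04 to 0.13; in panel b, 4 consecutive genes lie between 0.55 and 1.34, and the tallest bar is a gene of 180 bp below the low-value minimum with 1 fragment per library.

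In all, 64 of the 2430 genes (2.63%) differed at least 2-fold, 25 higher and 39 lower in TB. Of these, 2 of the higher genes were listed at 0 in WT and 13 of the lower genes at 0 in TB, the shallower library, which leaves 23 higher and 26 lower among genes above 0 in both. Fragments were recovered for 26 of the 64. The 95% counting interval of the fold excluded 1 for 7 of 12 higher and 11 of 14 lower genes. Own-locus genes of at least 300 bp made up 5 of the higher and 7 of the lower genes, and for all 12 the interval excluded 1. Exclusion of 1 was common at this depth: it held for 615 of all 1546 passing own-locus genes with fragments, while the whole interval lay beyond 1.5-fold for 30, 11 higher and 19 lower. By the fixed rule, the second-highest gene was B932_2267, 174 bp at positions 2272029 to 2272202, with 811 FPKM in TB and 153 in WT (log2 ratio 2.40). It rested on 3 TB and 2 WT fragments, and its interval of -0.72 to 5.99 includes equal levels. The lowest was B932_2782, 210 bp at positions 2773480 to 2773689, with 47.6 FPKM in TB and 375.9 in WT (log2 ratio -2.95), from 1 TB and 27 WT fragments, with an interval of -8.34 to -0.38. The second-lowest was B932_2222 in a locus of 2 genes at positions 2226080 to 2226714, with 596 FPKM in TB and 2463 in WT (log2 ratio -2.04). If B932_2222 is at least 174 bp long and holds whole fragments, at least 106 TB and 1375 WT fragments lay behind it. The interval at that number was -2.35 to -1.76.

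Well-counted genes that were higher in TB included one of 1029 bp at positions 2089055 to 2090083, which stood at 695 FPKM in TB and 275 in WT (log2 ratio 1.34, interval 1.21 to 1.47). A gene of 336 bp at 1311593 to 1311928 reached 1756 FPKM against 735 (1.26, interval 1.03 to 1.48). A gene of 1398 bp at 1074539 to 1075936 reached 497 against 239 FPKM (1.05, interval 0.93 to 1.18). Adjacent genes of 999 bp and 2871 bp, which start at 331916 and 332918, both had a log2 ratio of 1.04. Of the merged loci, 1 gene within 1349663 to 1351307 stood at 6542 FPKM in TB and 2571 in WT (1.35), and 1 gene within 388580 to 390005 at 2225 and 879 FPKM (1.34).

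Well-counted genes that were lower in TB included one of 360 bp at positions 1963083 to 1963442, with 2162 FPKM in TB and 5165 in WT (log2 ratio -1.26, interval -1.40 to -1.11). A gene of 486 bp at 382645 to 383130 stood at 4855 FPKM in WT and 2099 in TB (-1.21, interval -1.32 to -1.10). A gene of 450 bp at 27737 to 28186 stood at 6651 FPKM in WT and 3156 in TB (-1.08, interval -1.17 to -0.98). Adjacent genes of 771 bp and 297 bp, which start at 166324 and 167131, had log2 ratios of -1.18 and -1.43.

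**Figure D3:**
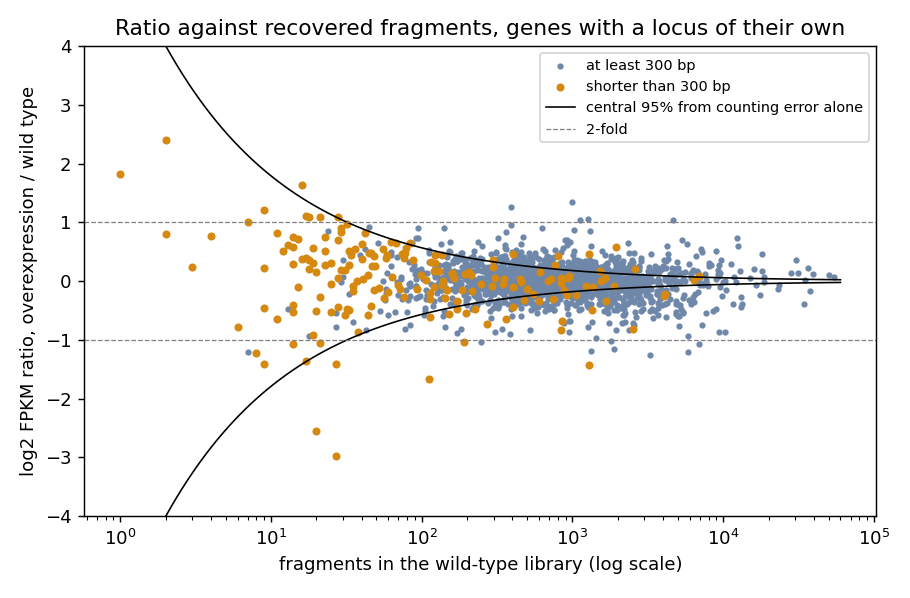
Log2 ratio of TB to WT FPKM against the recovered fragments in the wild-type library (log scale) for genes with a locus of their own and fragments in both libraries; orange points are shorter than 300 bp, blue points are longer, black lines enclose the central 95% that counting error alone gives at the library depths, and dashed lines mark 2-fold. Of the 18 points beyond 2-fold with fewer than 100 WT fragments 17 are orange, and of the 15 with more 12 are blue, all of them outside the black lines.

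Neighbouring genes tended to move together. Among 1121 pairs of adjacent own-locus genes with at least 50 TB fragments each, the log2 ratios correlated with Pearson's r = 0.31 and Spearman's rho = 0.26 across pairs, and the highest r in 1000 shuffles of the genes was 0.11. There were 9 runs of at least 3 consecutive passing genes with log2 ratios of at least 0.5 in 1 direction, 4 higher and 5 lower in TB. Shuffled gene orders gave a median of 1 run and at most 4. Of the higher runs, 4 genes at positions 65154 to 69064 had log2 ratios of 0.50 to 0.72, and 4 genes at 2088051 to 2093063 had ratios of 0.55 to 1.34. A run of 3 genes at 3073308 to 3076794 had ratios of 0.62 to 0.93. Of the lower runs, 3 genes at 1962058 to 1964672 had ratios of -1.26 to -0.67, 3 genes in 1 locus at 1674440 to 1675558 had ratios of -1.13 to -0.78, and 3 genes at 2257921 to 2259764 had ratios of -1.88 to -1.16. With 1 gene per locus there were 3 runs, against a median of 0 and at most 5 in shuffled orders.

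The lower run that starts at 2257921 contains 1 of 3 loci of 635 bp with 2 genes each, which lie within 66 kb and include B932_2222. Summed over the 6 genes, FPKM was 3640 in TB and 11755 in WT (log2 ratio -1.69). Of the 6 genes, 4 were at least 2-fold lower in TB, with log2 ratios of -2.04, -1.88, -1.71 and -1.21. The other 2 genes reached at most 8.71 FPKM in either library. The shortest length with whole fragments was 342 bp for the genes at -2.04, -1.71 and -1.21. It was 297 bp for the gene at -1.88. The 4 lower genes may therefore not be 4 separate changes. Whether the 3 loci are near-identical in sequence, so that fragments of one could be counted for another, was not examined.

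Short genes dominated the extremes of the FPKM scale. A single fragment was worth 180.3 FPKM in TB and 51.2 in WT at 180 bp, and 8.42 and 2.64 FPKM at 300 bp. Of the 10 genes with the highest mean, at 35846 to 86560 FPKM, 9 had a locus of their own, of 153 to 321 bp. Their log2 ratios, over all 10, lay between -0.24 and 0.58. All 179 own-locus genes of up to 150 bp were listed at 0 in both libraries. Of the 40 own-locus genes from 153 bp to below 174 bp, 7 were at 0 in both. A value of 0 at up to 150 bp therefore cannot be read as absent expression. At 153 bp, 3 genes had the same WT value of 1258.34 FPKM and were listed at 0 in TB. In total, 303 genes were listed at 0 in both libraries, the 179 short ones included, 36 in TB only and 2 in WT only. Of the genes at 0 in TB only, 11 lay above the 75th percentile of WT, and 1 of those at 0 in WT only lay above the 75th percentile of TB. For the 13 own-locus genes at 0 in TB with recovered fragments, WT held at most 8 fragments, and the WT level would have given at most 2.5 fragments in TB. A TB count of 0 allows up to 3, so no loss of these 13 transcripts was detectable at this depth. They are not the same set as the 13 genes at 0 in TB among the 2-fold lower genes. Most of that set lie in merged loci or are too short for a recovered count, and were not assessed.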

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

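The alternatives to own-locus length, counting interval, library agreement and neighbour runs were chosen after the values were seen; the others were set beforehand. Of 54 alternatives, 42 gave the same result. For counts of genes or runs this means within 1.5-fold of the reported count, and for Pearson's r a value close to the reported one. Of the 42, 24 were scaling and pseudocount alternatives of the 4 genes named by identifier. Their ratios all stayed within the counting interval and none reversed. This was largely fixed in advance, because the scalings moved log2 ratios little and the intervals of B932_2267 and B932_2782 were wide. These 24 therefore say little about stability. The 25 higher genes became 87 at 1.5-fold, 7 at 3-fold, 5 among own-locus genes of at least 300 bp and 7 among those whose counting interval excludes 1. The 39 lower genes became 97, 19, 7 and 11 in the same order, and 64 with no filter on low values, which admits more genes. The other settings gave 22 to 35 higher and 26 to 39 lower genes; with a pseudocount of 0, which leaves out genes at 0, they were 23 and 26. The scalings moved log2 ratios by -0.026 to 0.032. Pearson's r was 0.955 over all genes with no filter. By construction a higher threshold or fewer genes lowers a count. The 9 runs of neighbours became 3 at a log2 threshold of 0.75 and 3 with 1 gene per locus. The alternatives set beforehand for gene lists, pqq genes and the authors' own calls were not run, because the table holds no gene names and no calls. No paired analysis was possible because each strain has 1 library, and for the same reason none could be left out. Depth limits short genes most, TB above all.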

Other observations

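The tests on the 22-fold gene, on the genes at 0 and on the short genes' intervals, widened or not, were chosen after the result was seen, and the other simulations of counting error were set after the 2-fold genes were known but before the simulated numbers were. The hypotheses below were found and tested on the same 2 libraries.

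B932_1170 was 22.1-fold higher in TB. Counting error is argued against by the lower bound of its log2 interval, 4.35 at the shortest length, from 174 bp upwards, that gives whole fragments. That bound holds only if the gene is at least 174 bp long and fragments in its merged locus are whole. A gain of the surrounding DNA, or of its transcription as a block, is argued against by the other 3 genes of the locus, whose highest log2 ratio was 0.13. The hypothesis that this is the gene the strain was built to overexpress stays open: 0 of the 3543 identifiers are paired with a gene name, so the table cannot decide it.

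Among own-locus genes with recovered fragments, 14 of the 165 passing genes shorter than 300 bp and 12 of the 1381 longer ones differed at least 2-fold. With equal levels and counting error alone, 1000 simulations gave a median of 10 short genes with the central 95% between 5 and 15, so the number 14 alone does not argue against counting error. For 6 of the 14 the 95% counting interval excluded 1, against a simulated median of 2, a central 95% of 0 to 5 and a highest of 7; after widening the intervals for the 165 short genes compared (Bonferroni), 3 excluded 1, with bounds nearest to equal levels of -0.99 (297 bp, start 167131), -0.12 (189 bp, start 754326) and -0.03 (207 bp, start 3304552), the last 2 narrowly. The simulations took the genes that passed on their observed values and did not reapply the low-value minimum. The observed 6 and the simulated 0 to 5 are therefore not fully alike, and no conclusion is drawn from them. The 3 widened intervals argue against counting error as the cause of all 14, and for the other 11 it stays open. For the longer genes the simulations gave a median of 0, an upper end of the central 95% of 1 and a highest value of 1, which argues against counting error for those 12 as a set; a difference between the strains or between single cultures or library preparations stays open there, since each strain has 1 library.

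Of the 1798 own-locus genes of at least 300 bp, 31 were listed at 0 in both libraries, and 28 of these share their exact length with another of the 31. In 1000 random draws of as many genes the median was 2 and the highest 10. Shared lengths show that many of these genes come in sets of equal length, but not why they were at 0. Uncounted fragments of near-identical copies and truly silent copies would look the same here, and other causes were not tested. The 2 most frequent lengths were 1472 and 2736 bp, with 5 genes each and no other own-locus gene of either length, and each 1472 bp gene lay 661 bp from a 2736 bp gene. That arrangement may be a repeated ribosomal RNA operon, which needs the sequence to check. For these genes at 0, no biological explanation was tested.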
